A study of Mus musculus and Homo sapiens with 18 samples.

How the data were processed

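Poly(A)-selected RNA was sequenced from 18 bladder carcinoma libraries, prepared with a stranded mRNA kit per the labels' protocols. Salmon is the only tool given in the submitters' processing notes, without a version. The same notes name GRCh38 (hg38) and GRCm38 (mm10) without saying which step used which. The authors deposited estimated counts and TPM values (transcript abundances scaled to a fixed total) in separate tables for the mouse tumours, the mouse line CUUC-G and the human line MGHU3. The deposited estimated counts of the tumours were given for 147828 transcripts, each with its gene identifier, symbol and biotype per the file headers, and were summed here to 55858 genes. The deposited CUUC-G table held whole numbers for the same 55858 gene identifiers. In 153 of its gene and library values the count was 0 while the authors' TPM was above 0, so these whole numbers are rounded estimates. The deposited MGHU3 estimated counts were given for 228754 transcripts under Ensembl transcript identifiers that the files do not pair with genes, and no human annotation was used here. That table was therefore analysed by transcript, and IGFBP5 itself, the gene lists and the comparisons of MGHU3 with the mouse data were not analysed here.

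Groups and replicate numbers came from the sample labels. The columns of the CUUC-G table marked mI were taken as the sgIgfbp5 samples because the labels mark the IGFBP5-targeted MGHU3 libraries with hI; the table itself does not spell this out. The number of table columns matched to no sample was 0. All estimated counts were rounded to whole numbers. Mouse symbols came from the tumour table for all 55858 identifiers. Positions came from GENCODE M21 on GRCm38, in which 51460 of these identifiers were found without their version; only 35 had the same version, so the authors' annotation was another release.

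The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with TMM scaling, the filterByExpr filter, robust dispersion, Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. The test was two-sided and used only the libraries of the comparison. Standard errors were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F. CPM values were computed from the estimated counts with TMM-scaled library sizes unless stated otherwise. A fold against a group without any count was given as a lower bound, with a floor of 3 counts over the group; a gene with 1 to 3 counts in a group was given its ratio with an exact 95% binomial interval. Intervals and floors cover counting error only.

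Before the data were examined, 51 gene lists were fixed, together with the tests, the alternatives and a rule for the genes named. The rule took Igfbp5, and per comparison the 6 largest increases and the 6 largest decreases among named protein-coding genes past the threshold with an average log2 CPM of at least 2 and no overlap between the groups. It added up to 4 members, by p, of each of the 6 lists with the smallest p, up to 6 members of the IGF axis list by p, and for the overlap of the mouse comparisons 5 genes per pair of directions. Of the human transcripts, which have no gene names here, 2 per direction are given. Some genes this rule took are not reported. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Through older symbols in the mouse RefSeq table of GRCm38.p6, 6 list symbols were matched; 1 symbol, Rigi, stayed unmatched. Overlaps of calls were tested with Fisher's exact test, two-sided. Sex-linked genes were read as a quality check.

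The alternatives were RLE size factors, library size only, DESeq2 1.42.0, no low-count filter (a total of at least 1), a filter of 1 CPM in 3 libraries, dispersion that was not robust, limma on log2(TPM + 1) with a mean TPM of at least 1, a pseudocount of 0.1, no TPM filter, the replicate number as a block, each library left out, and a fold of at least 2. For lists, the correlation estimated per list and fry were run as well. Counts for autosomal genes alone were added after the data were seen.

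The edgeR step was tested on simulated counts. In the relapse simulation of 14373 genes, 48 of 50 genes changed 2-fold and 40 of 50 changed 1.5-fold were recovered. In the CUUC-G simulation of 14553 genes these numbers were 44 and 35. In the MGHU3 simulation of 44970 transcripts, 3 of 50 transcripts changed 2-fold, 21 changed 4-fold and 28 changed 8-fold were recovered. Most features were left unchanged in these simulations, 14173 of 14373 genes in the relapse one. In the data 73.5% of genes were called at relapse and 70.8% in CUUC-G, so recovery and scaling under such wide change were not tested. The list test recovered 3 of 3 lists shifted by 1 on the log2 scale in each mouse simulation and called 0 of the 42 and 40 others. Genes were drawn independently there, so false list calls from correlation between genes were not tested. In the comparison of chromosome medians, 2 of 2 chromosomes shifted by 0.5 on the log2 scale were found, and 0 without a shift. The largest differences in the data were smaller (-0.339 at relapse and -0.382 in CUUC-G), so recovery at their size was not tested. Genes were shuffled there, so false findings from neighbouring genes regulated together were not tested. Every pair of replicates differed by more than counting noise, with a mean chi-square per feature between 2.64 and 41.94, so none was counted as a repeated library. Whether replicates came from separate animals or cultures is not given in the labels, so p-values measure the spread between these libraries, which may be technical.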

Results

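RNA was sequenced from 18 libraries in 6 groups of 3. The first pair of groups was tumours of a genetically engineered mouse model (GEMM) of bladder carcinoma, labelled as relapsed after chemotherapy with cisplatin and gemcitabine, and control tumours. The second pair was the mouse line CUUC-G with a guide RNA against Igfbp5 (sgIgfbp5) or a control guide (sgScr). The last pair was MGHU3, a human bladder cancer cell line, with IGFBP5 targeted or with sgScr. IGFBP5 is a secreted protein that binds insulin-like growth factors. The labels call the targeted samples knockdowns, while the series design describes knockouts. Total estimated counts, in units of 1e6, lay between 18.965 and 21.757 in the tumour libraries, between 19.211 and 20.73 in CUUC-G and between 19.367 and 21.064 in MGHU3.

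The first comparison asked how relapsed tumours differed from control tumours. Igfbp5 (ENSMUSG00000026185.9; GRCm38 chromosome 1, 72857932 to 72874884, minus strand) was low in both groups and higher at relapse. It had 0.459 ± 0.381 CPM in the control and 2.46 ± 0.698 CPM in the relapsed libraries (SD, n = 3), a log2 fold change of 2.44 ± 0.44 (SE; edgeR adjusted p = 1.97e-05). These levels rest on 27 counts over the control libraries and 149 over the relapsed ones. Control replicate 2 held 17 of the 27, and without it the log2 fold change was 3.32. On log2(TPM + 1) without a filter, where low genes are compressed, the difference was 0.45 with a limma adjusted p of 0.071.

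Genes of cholesterol synthesis, inflammatory cytokines, cell division, glycolysis and heat shock proteins rose in the relapsed tumours. All 23 measured genes of cholesterol synthesis rose. Idi1, which makes an isoprenoid precursor, went from 46.0 to 381 CPM, a log2 fold change of 3.05 ± 0.04 (SE, n = 3), and Cyp51 rose by 1.78 ± 0.03. Among 21 NF-kB and inflammatory cytokine genes, 19 rose and 2 fell. The chemokine Cxcl5 went from 0.145 ± 0.0809 to 841 ± 17.1 CPM (SD, n = 3), Ccl2 from 5.05 to 478 CPM, Cxcl1 by 5.55 ± 0.08 on the log2 scale and Ptgs2, an inducible prostaglandin synthase, from 136 to 1340 CPM. Of 25 G2M cell cycle genes, 22 rose, 1 fell and 2 did not pass. The proliferation marker Mki67 rose by 1.45 ± 0.04 on the log2 scale, Cenpf by 2.19 ± 0.07, Kif20a by 0.98 ± 0.04 and the mitotic kinase Plk1 by 1.27 ± 0.05. Of 31 DNA replication genes, 25 rose, 3 fell and 3 did not pass. The log2 fold change was 2.96 ± 0.04 for the ribonucleotide reductase subunit Rrm2, 1.03 ± 0.04 for Mcm7, 0.91 ± 0.04 for Mcm5 and 1.18 ± 0.06 for Tyms. Of 28 hypoxia and glycolysis genes, 23 rose, 4 fell and 1 did not pass, with 1.64 ± 0.03 for lactate dehydrogenase Ldha, 1.28 ± 0.03 for Pkm, 2.11 ± 0.04 for Bnip3 and 1.26 ± 0.03 for Aldoa. Of 15 heat shock genes, 13 rose, 1 fell and 1 did not pass, with 2.19 ± 0.04 for Cryab, 1.81 ± 0.04 for Hspb1, 1.08 ± 0.02 for Hsp90ab1 and 1.01 ± 0.03 for Hsp90aa1.

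Camera with a preset correlation called 22 of 45 tested lists, 15 up and 7 down. The adjusted camera p was 5.44e-10 for cholesterol synthesis, 1.66e-07 for cytokines, 2.82e-06 for G2M, 6.22e-05 for hypoxia and glycolysis, 0.000103 for DNA replication and 0.000185 for heat shock proteins. With an estimated correlation 0 lists were called. The adjusted p with an estimated correlation was then 0.118 for cholesterol synthesis, cytokines and G2M, 0.175 for heat shock proteins, 0.189 for DNA replication and 0.199 for hypoxia and glycolysis. Adjusted over the list alone, 23 G2M and 26 DNA replication genes rose, and the numbers that rose in the 4 other lists were those over all genes.

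Several epithelial marker lists also rose from low levels. The filter left 11 of 17 luminal, 11 of 18 basal, 6 of 18 squamous and 9 of 20 junction genes. Over all members, the median went from 0.561 to 2.75 CPM for luminal and from 0.244 to 0.712 CPM for basal markers. It went from 0.0241 to 0.196 CPM for squamous and from 0.108 to 0.361 CPM for junction genes (CPM by library size), so most of these stayed low. Among luminal urothelial markers 8 of 11 tested rose and 1 fell (adjusted p = 0.00688 by camera and adjusted p = 0.199 with an estimated correlation), and among basal markers 8 of 11 rose and 1 fell (adjusted p = 0.0199 by camera and adjusted p = 0.191 with an estimated correlation). Squamous genes rose for 5 of 6 tested and epithelial junction genes for 5 of 9, with camera adjusted p values of 0.0201 and 0.0441 and an adjusted p with an estimated correlation of 0.199 and 0.201. Krt8, a keratin of simple epithelia, had 1 count over the control libraries and 8583 over the relapsed ones, a ratio of 8630 (95% interval 1550 to 341000). Genes that fell included 14 of 20 fibroblast markers, with 5 rising, 9 of 13 smooth muscle markers, with 3 rising, and 10 of 12 antigen presentation genes, with 0 rising. Their camera adjusted p values were 0.0255, 0.0294 and 0.0139, and the adjusted p with an estimated correlation was 0.199, 0.199 and 0.191. Targets of p53 fell for 16 and rose for 5 of 26 (camera adjusted p = 0.016; adjusted p = 0.191 with an estimated correlation). ATF4 and unfolded protein response genes fell for 17 and rose for 7 of 28, and PI3K AKT FOXO targets fell for 15 and rose for 3 of 24. Their camera adjusted p values were 0.016 and 0.0306, and the adjusted p with an estimated correlation was 0.205 and 0.191.

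The remaining lists past the threshold went up, apart from the sex-linked one. Interferon response genes rose for 18 and fell for 4 of 24, senescence secretory genes rose for 15 and fell for 6 of 21, fatty acid genes rose for 13 and fell for 4 of 19, genes of gemcitabine transport and metabolism rose for 10 and fell for 2 of 16, and macrophage markers rose for 6 of 7. The camera adjusted p was 0.00946, 0.016, 0.016, 0.0245 and 0.0441 in this order, and the adjusted p with an estimated correlation was 0.189, 0.191, 0.199, 0.191 and 0.199. Epithelial junctions, smooth muscle and macrophage markers were past the threshold with all libraries and not with some of them left out. Epithelial junctions lost the call when any library other than relapsed replicate 1 was left out (camera adjusted p between 0.0516 and 0.0767). The tested macrophage markers stayed low, with Cd14 the highest of that list at 21.1 CPM in the relapsed libraries.

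The largest increases by the fixed rule were in Cck, a peptide hormone gene, Mael, Krt8, Cxcl5, Pcdh17 and Xlr. Cck had 0 counts in the control and 104 ± 3.80 CPM in the relapsed libraries (SD, n = 3), at least 2110-fold higher, Mael was at least 1050-fold, Pcdh17 at least 646-fold and Xlr, of a family of similar genes, at least 576-fold higher. The largest decreases were in Ddx3y, Eif2s3y, Cdsn, Uty, Nxf7 and Gpr141. Cdsn, which encodes the adhesion protein corneodesmosin, went from 685 ± 10.7 to 0.975 ± 0.234 CPM and Gpr141 from 102 to 0.248 CPM. Nxf7 had 2 counts over the relapsed libraries, a ratio of 480 (95% interval 132 to 3970). Of the IGF axis list 9 of 19 genes rose and 7 fell. The log2 fold change was 8.11 ± 0.18 (SE, n = 3) for Stc1, 4.30 ± 0.22 for Igf2, 1.46 ± 0.07 for Irs1, 0.91 ± 0.04 for Igfbp7, -1.10 ± 0.05 for Igfbp3 and -1.53 ± 0.03 for Htra1.

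The Y-linked genes separated the groups completely. Ddx3y had 74.2 ± 4.02 CPM (SD, n = 3) in the control libraries and 0 counts in the relapsed ones, at least 1490-fold lower, and Eif2s3y was at least 802-fold lower. Uty had 3 counts over the relapsed libraries, a ratio of 566 (95% interval 193 to 2750), and Kdm5d went from 25.1 to 0.379 CPM. Xist, the transcript of the inactive X chromosome, had 0.0845 ± 0.0634 CPM in the control and 483 ± 20.2 CPM in the relapsed libraries. The sex-linked list, 4 of 5 lower, had a camera adjusted p of 0.0421 and an adjusted p of 0.267 with an estimated correlation. Each gene group above moves with this difference between the groups.

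Of 14373 genes tested, 5260 were higher and 5299 lower in the relapsed tumours at an edgeR adjusted p under 0.05, of which 1899 and 1724 changed at least 2-fold. Libraries of a group were close to each other, with an edgeR common biological coefficient of variation of 0.052. Whether they came from separate tumours is not given in the labels, so these p-values and standard errors may not extend to other tumours. On autosomes alone, a count added after the data were seen, 5013 were higher and 5069 lower. Relapsed and control libraries came from animals of different sex, as the sex-linked genes show, so source and relapse coincide and no fit separates them. The series calls these samples tumours, but immune and vascular markers had a median of 0.0169 CPM in the control libraries. The relapsed libraries were nearly alike to the sgScr libraries of the line CUUC-G (r of mean log2 CPM 0.991, with 272 of 15366 genes differing 2-fold). These values argue against tissue that holds immune and vascular cells, more directly for the relapsed than for the control libraries. Whether cells grown from tumours were sequenced is not given in the labels. On log2(TPM + 1), limma called 3529 higher and 5139 lower, so higher calls made up 40.7% against 49.8% with edgeR.

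The second comparison asked what changed when Igfbp5 was targeted in CUUC-G. Igfbp5 was lower in the sgIgfbp5 libraries, with 0.490 ± 0.108 CPM against 1.97 ± 0.814 CPM with sgScr (SD, n = 3). The counts give a ratio of 4.03 (log2 standard error 0.42; edgeR adjusted p = 0.00125), from 114 counts over the sgScr and 30 over the sgIgfbp5 libraries. A guide RNA need not lower the transcript, so the count checks the labels only in part. On log2(TPM + 1) without a filter the difference was -0.36 with a limma adjusted p of 0.074.

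**Figure D1:**
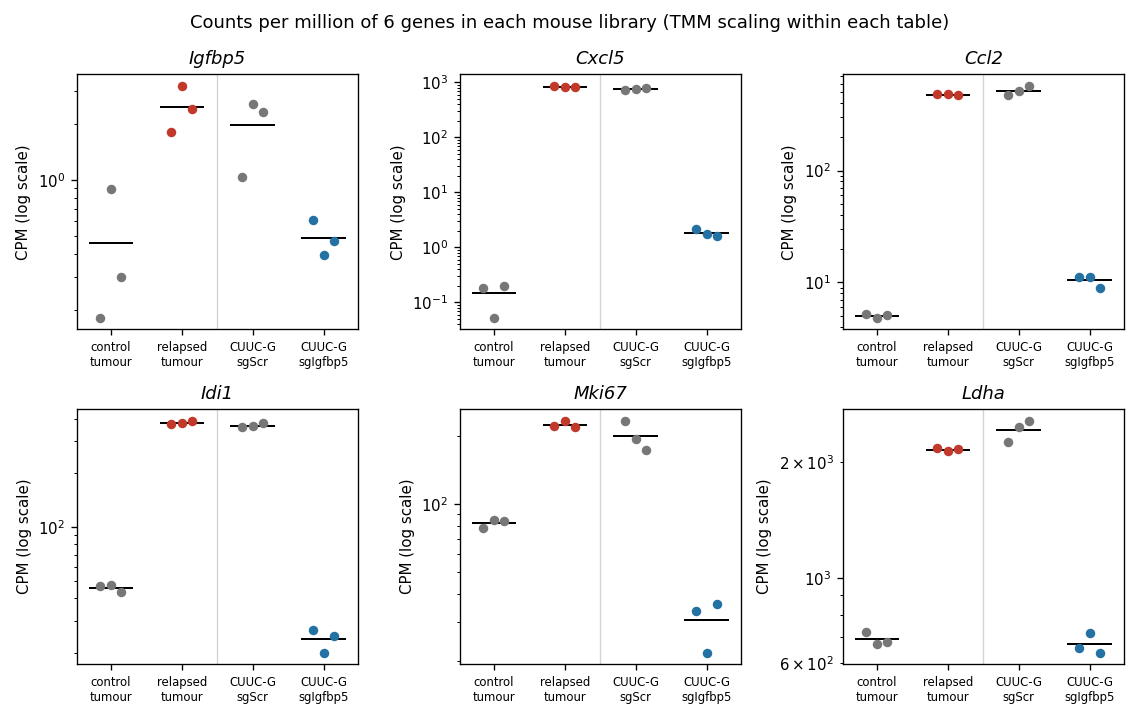
CPM on a log axis of 6 genes in each of the 12 mouse libraries, with a point per library and a line at the mean of each group of 3; the 2 tables were scaled separately. Igfbp5 lay between 0.182 and 0.894 CPM in control and between 1.80 and 3.19 CPM in relapsed tumours, and between 1.04 and 2.56 CPM with sgScr and 0.393 and 0.606 CPM with sgIgfbp5.

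Genes of cholesterol synthesis, cell division, DNA replication, cytokines, glycolysis and the interferon response, which rose at relapse, fell in sgIgfbp5 CUUC-G. Of the lists up at relapse, the luminal, epithelial junction, macrophage and gemcitabine lists were not past the camera threshold here (adjusted p = 0.0622, 0.0941, 0.161 and 0.23). All 23 cholesterol synthesis genes fell, with a log2 fold change of -3.94 ± 0.10 (SE, n = 3) for Idi1 and -2.53 ± 0.07 for Cyp51. All 25 G2M genes fell. The cyclin Ccna2 went from 159 ± 4.45 to 34.4 ± 0.489 CPM (SD, n = 3), Ccnb2 from 69.9 to 8.74 CPM, the kinetochore gene Nuf2 from 56.3 to 8.91 CPM and Birc5 from 85.6 to 13.7 CPM. Of 22 cytokine genes, 19 fell, 2 rose and 1 did not pass. Cxcl5 went from 758 to 1.83 CPM, Ccl2 from 519 to 10.4 CPM, Cxcl1 from 150 to 5.74 CPM and Ptgs2 from 1180 to 129 CPM. Of 28 hypoxia and glycolysis genes 23 fell, 3 rose and 2 did not pass, with a log2 fold change of -5.53 ± 0.14 for Adm, -2.80 ± 0.08 for Pfkl, -2.59 ± 0.08 for Egln3 and -2.40 ± 0.09 for the glucose transporter Slc2a1. Of 31 DNA replication genes 25 fell, 2 rose and 4 did not pass, with -2.99 ± 0.07 for Rrm2, -1.83 ± 0.07 for Tyms, -1.79 ± 0.08 for Pold1 and -2.03 ± 0.10 for Gins2. Of 23 interferon response genes 21 fell and 2 rose, with -2.78 ± 0.11 for the chemokine Cxcl10, -3.17 ± 0.20 for Ifit3 and -2.13 ± 0.16 for Irf7.

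Camera called 21 of 44 tested lists, 2 up and 19 down. The adjusted camera p was 9.64e-11 for cholesterol synthesis and 8.74e-10 for G2M, and both were also called with an estimated correlation (adjusted p = 0.04 each). It was 2.28e-06 for cytokines, 5.87e-06 for hypoxia and glycolysis, 2.99e-05 for DNA replication and 0.000133 for interferon response, each with an adjusted p of 0.205 with an estimated correlation. Adjusted over the list alone, the numbers that fell in these 6 lists were those over all genes. Mesenchymal, contractile and matrix genes, measured here in a cell line, fell as well. Lower were 16 of 20 mesenchymal genes, with 3 rising, 15 of 18 fibroblast markers, with 3 rising, and 11 of 13 smooth muscle markers, with 1 rising. So were 16 of 21 matrix remodelling enzymes, with 3 rising, 16 of 23 TGF-beta targets, with 4 rising, and 15 of 22 integrins and laminins, with 4 rising. In this order, the camera adjusted p was 0.000206, 0.000211, 0.000796, 0.000241, 0.00159 and 0.00433. The adjusted p with an estimated correlation was 0.205 for the mesenchymal, fibroblast, smooth muscle and TGF-beta lists, 0.165 for the matrix enzymes and 0.219 for integrins and laminins. Homologous recombination genes fell for 24 of 30, with 5 rising, NRF2 targets for 14 of 19, with 1 rising, senescence secretory genes for 15 of 21, with 5 rising, and heat shock genes for 10 of 15, with 2 rising. Their camera adjusted p was 0.00128, 0.00128, 0.0033 and 0.00653, and the adjusted p with an estimated correlation was 0.343, 0.219, 0.334 and 0.219. Basal urothelial markers fell for 8 of 10, fatty acid genes for 13 of 19, with 5 rising, and squamous genes for 5 of 6, with 1 rising. Their camera adjusted p was 0.014, 0.0217 and 0.0416, and the adjusted p with an estimated correlation was 0.205, 0.219 and 0.219. The 2 lists that went up were ribosomal proteins, with 20 of 36 rising and 2 falling, and p53 targets, with 16 of 27 rising and 5 falling. Their camera adjusted p was 0.0217 and 0.0416, and the adjusted p with an estimated correlation was 0.763 and 0.219. The squamous, p53 and ribosomal lists were not past the threshold in some fits with a library left out, nor were ribosomal proteins with fry (adjusted p = 0.0828).

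The largest decreases were in Cck, Nos2, Slco4a1, Brinp3, Prl2c3 and Galnt13, each with 0 counts in the sgIgfbp5 libraries. Cck had 123 ± 18.6 CPM (SD, n = 3) with sgScr and was at least 2520-fold lower, and Nos2, the inducible nitric oxide synthase, was at least 394-fold lower. The bound was 339-fold for Slco4a1, 338-fold for Brinp3, 255-fold for Prl2c3 and 179-fold for Galnt13. The largest increases were in Try5, Cdsn, Prr32, Tfap2a, Sspo and Ebf3. Cdsn went from 1.55 ± 0.388 to 790 ± 53.8 CPM, the transcription factor gene Tfap2a from 0.158 to 28.7 CPM, Prr32 from 0.0701 to 16.9 CPM, Sspo from 0.119 to 19.4 CPM and Ebf3 from 0.0717 to 11.4 CPM. Try5 went from 0.0706 to 69.1 CPM. Try5 and Prl2c3 belong to families of near-identical genes whose reads can be shared, so their values are uncertain. In the IGF axis list 9 of 19 genes rose and 7 fell. Stc1 went from 42.7 to 0.113 CPM and Igfbp7 from 278 to 35.5 CPM, while the log2 fold change was 2.48 ± 0.08 (SE, n = 3) for Igf2bp1, 2.07 ± 0.11 for Igf2bp3, 1.95 ± 0.10 for Insr and 1.56 ± 0.07 for Igfbp3. Xist rose from 411 ± 96.5 to 1430 ± 394 CPM, and Kdm5d had 0.504 CPM with sgScr and 0.468 CPM with sgIgfbp5 (edgeR adjusted p = 0.869).

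Of 14553 genes tested, 5316 were higher and 4989 lower with sgIgfbp5 at an edgeR adjusted p under 0.05, of which 2118 and 2441 changed at least 2-fold. The balance of directions depended on the scaling, with 6043 higher and 4389 lower by library size alone and 4834 higher and 5376 lower with DESeq2. Scaling by library size alone moved the median log2 fold change of these genes from 0.059 to 0.17, and the lists called here and the genes named by the fixed rule kept their direction except Kdm5d.

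**Figure D2:**
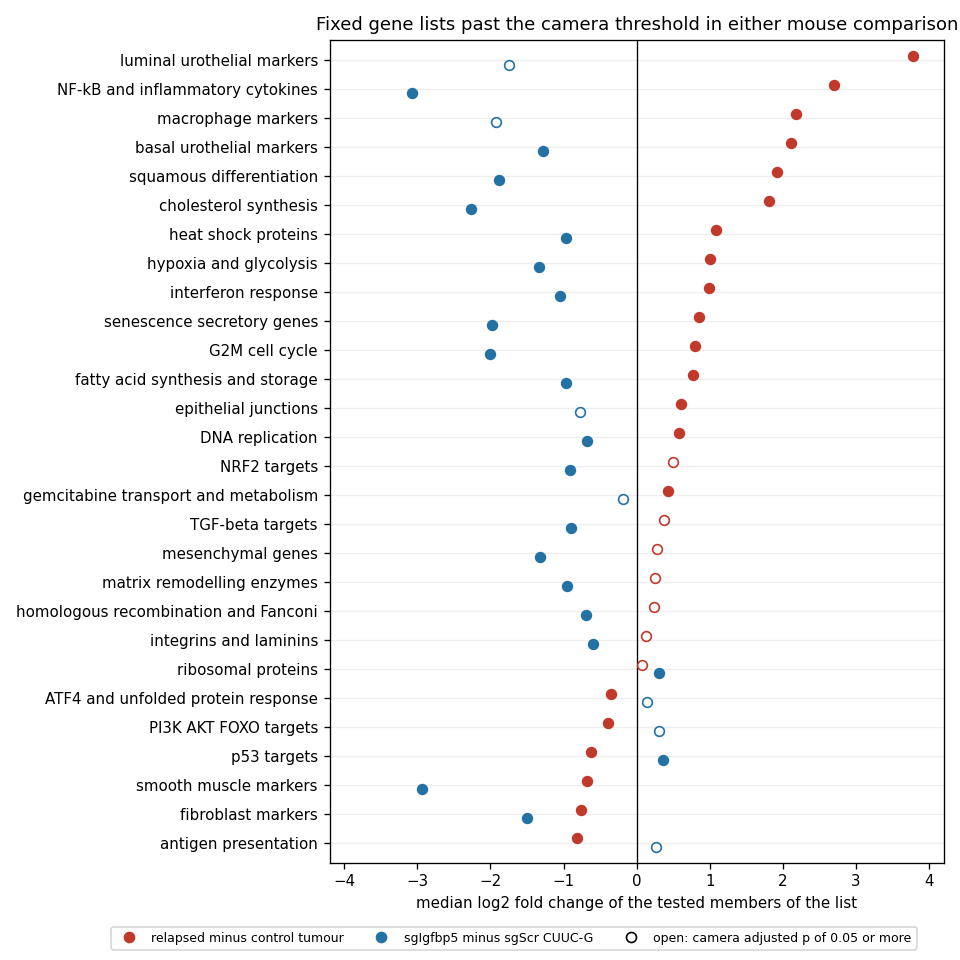
Median log2 fold change of the tested members of 28 fixed lists, those past the camera threshold in at least 1 mouse comparison, the sex-linked list left out; filled points are past an adjusted p of 0.05 with the preset correlation. The medians of 25 lists have opposite signs in the 2 comparisons.

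The third comparison used the estimated transcript counts of MGHU3. Of 44970 transcripts tested, 402 were higher and 754 lower with IGFBP5 targeted at an edgeR adjusted p under 0.05, of which 179 and 443 changed at least 2-fold. ENST00000562946 had 0 counts with sgScr and 30.8 ± 2.29 CPM with IGFBP5 targeted (SD, n = 3), at least 599-fold higher, and ENST00000648440 was at least 431-fold higher. ENST00000255006 had 48.2 ± 0.892 CPM with sgScr and 0 counts with IGFBP5 targeted, at least 959-fold lower, and ENST00000360270 was at least 862-fold lower. With the replicate number as a block none of these 4 transcripts was past the threshold (edgeR adjusted p between 0.174 and 0.192). Their log2 fold changes under the block were those of the main fit, 12.24, 11.78, -12.89 and -12.74 in the order above. With a library left out, ENST00000562946, ENST00000648440 and ENST00000360270 reached an edgeR adjusted p of 0.0536, 0.0671 and 0.0647. Transcripts of a gene share reads, so estimated counts of single transcripts are uncertain. With the replicate number as a block edgeR called 0 transcripts higher and 0 lower. The call counts also depended on single libraries. Without sgScr replicate 3 they were 12 higher and 42 lower, and without IGFBP5-targeted replicate 1, 2 or 3 they were 7 and 60, 0 and 23, and 8 and 70. At an unadjusted p under 0.05, edgeR counted 5319 transcripts without IGFBP5-targeted replicate 2, against 6966 with all libraries. DESeq2 called 1433 higher and 1664 lower with all libraries, so higher calls made up 46.3% of its calls against 34.8% with edgeR. The edgeR common biological coefficient of variation was 0.589, against 0.052 in the tumours and 0.1 in CUUC-G, both by gene.

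The last comparison asked how the genes that changed at relapse moved when Igfbp5 was targeted in CUUC-G. Of 13904 genes tested in both, 7947 were called in both, and 6625 of these (83.4%) went in opposite directions. Genes higher at relapse and lower with sgIgfbp5 numbered 3428, genes lower at relapse and higher with sgIgfbp5 3197, genes higher in both 624 and genes lower in both 698. The relapsed and sgScr CUUC-G libraries were nearly alike (r of mean log2 CPM 0.991) and enter the 2 contrasts with opposite signs, so opposite directions can arise without an effect of Igfbp5. Fisher's exact test, fixed beforehand, assumes independent lists (odds ratios 9.3, 6.47, 0.134 and 0.172 in the order above) and is no measure of such an effect. Across genes, Spearman's rho of the log2 fold changes was -0.607. Cxcl5, Tmem45a, Thbs2, Epb41l3 and Ccl7 were the genes higher at relapse and lower with sgIgfbp5 with the smallest p. The chemokine Ccl7 changed by 5.10 ± 0.05 at relapse and -5.97 ± 0.11 with sgIgfbp5 (log2, SE, n = 3). In the other direction were Cdsn, Atf3, Gadd45a, Txnip and Egr1, with -4.41 ± 0.07 and 4.61 ± 0.09 for the stress-induced transcription factor Atf3 and -4.25 ± 0.05 and 3.62 ± 0.08 for Gadd45a. Higher in both were Zfp521, Txnl4a, Nipsnap1, Hoxb7 and Pcdh17, with 1.57 ± 0.16 and 2.01 ± 0.11 for Zfp521. Lower in both were Tagln, Acta2, Myl9, Ccn2 and Gask1b, with -0.68 ± 0.03 and -3.60 ± 0.10 for Tagln and -0.72 ± 0.03 and -2.79 ± 0.09 for Acta2, both contractile genes. With the preset correlation 14 lists were called in both comparisons, 12 of them in opposite directions, and the fibroblast and smooth muscle lists fell in both. With an estimated correlation 0 lists were called at relapse, so none was called in both. The likeness of relapsed and sgScr libraries bears on the lists as on the genes.

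**Figure D3:**
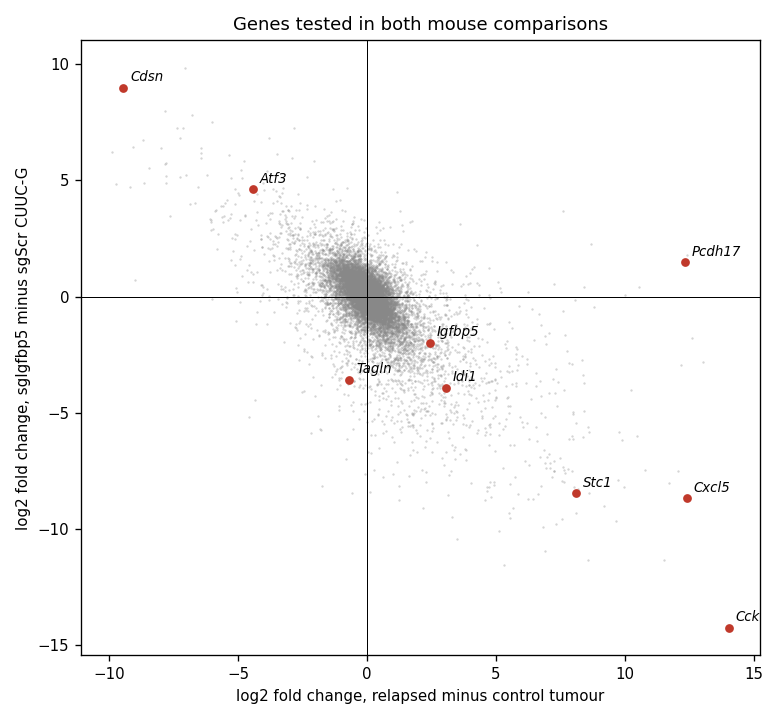
Log2 fold change of the relapsed against control tumours (x axis) and of sgIgfbp5 against sgScr CUUC-G (y axis), with a grey point for each of 13904 genes tested in both and named genes in red. The cloud runs from upper left to lower right; fitted values of genes without counts in a group depend on the prior count.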

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

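The direction of Igfbp5 was kept in every alternative that could test it, in both mouse comparisons. The log2 fold change at relapse lay between 2.03 and 3.32 when each library was left out, and in CUUC-G between -2.31 and -1.77. It was past the threshold except on log2(TPM + 1) without a filter, where it was 0.45 at relapse and -0.36 in CUUC-G; over all alternatives the adjusted p ran from 1.94e-08 to 0.071 and from 6.88e-06 to 0.074. The 2 alternatives with a TPM filter removed Igfbp5. Counts of mouse genes stayed within 1.5 times of the main count except with a fold of at least 2, which left 1899 higher and 1724 lower at relapse, 2118 and 2441 in CUUC-G, and 2043 of the genes called in opposite directions. The relapse table's median log2 fold change moved from 0.002 to -0.121 on log2(TPM + 1). At relapse 0 lists were called with an estimated correlation and 42 with fry; in CUUC-G 2 and 37. Lists near the threshold also lost their call with single libraries left out, with an adjusted p of up to 0.0767 for epithelial junctions, 0.0668 for smooth muscle, 0.058 for macrophage markers and 0.0649 for sex-linked genes at relapse, and up to 0.0903 for ribosomal proteins in CUUC-G; no list changed direction. The other mouse genes named by the fixed rule kept their call in every alternative that tested them, except Txnl4a at relapse, at 0.37 with an adjusted p of 0.0946 on log2(TPM + 1) without a filter. No alternative was run for single genes chosen after their values were seen. Kdm5d in CUUC-G was not called and turned to 0.02 with library size only and to 0.15 at the extreme of leaving out a library. In MGHU3, calls numbered 1433 higher and 1664 lower with DESeq2, 188 and 376 on log2(TPM + 1) without a filter, and 179 and 443 with a fold of at least 2. With each MGHU3 library left out in turn, they ran from 0 to 532 higher and from 23 to 695 lower; the cause of these differences was not tested. The labels do not say whether replicate numbers pair the samples. Same-numbered libraries showed little shared deviation over all features, which does not exclude pairing. The correlations were 0.01, 0.01 and 0.01 in the tumours, 0.04, 0.09 and -0.08 in CUUC-G, and 0, 0 and 0.01 in MGHU3. With the replicate number as a block, edgeR called 0 transcripts higher and 0 lower in MGHU3, where 5323 had an unadjusted p under 0.05; in the mouse comparisons it gave 5208 higher and 5264 lower at relapse and 5155 and 4882 in CUUC-G. The block also ended the calls of epithelial junctions (adjusted p = 0.071) and sex-linked genes (adjusted p = 0.0583) at relapse. Depth limits Igfbp5, with 27 and 30 counts over its low groups. The alternatives fixed beforehand for IGFBP5 and gene lists in MGHU3, for the difference between MGHU3 and CUUC-G and for calls shared with MGHU3 were not run, because its transcripts were not paired with genes.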

Other observations

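The tests of immune and vascular markers, of source animals, of male cells in the sgIgfbp5 libraries and of likeness between relapsed and sgScr CUUC-G libraries were chosen after the results they measure had been seen. All 4 mouse groups expressed mesenchymal genes at high levels, with a median of 190 CPM over the mesenchymal list in control and 333 CPM in relapsed tumours, 323 CPM in sgScr and 82.6 CPM in sgIgfbp5 CUUC-G (CPM by library size). Immune and vascular markers were near the floor in the tumour libraries: T and NK cell and B and plasma cell markers had a median of 0 CPM in control and in relapsed libraries, and endothelial markers 0.0851 and 0.0821 CPM. Single members stood out, chosen here after their values were seen. The endothelial marker Kdr went from 1.44 to 156 CPM at relapse and from 152.5 to 7.79 CPM with sgIgfbp5, and the keratin Krt19 from 4.62 to 260.7 CPM and from 312.9 to 34.8 CPM. Of the tested endothelial markers, 3 of 6 rose and 2 fell at relapse, and 1 of 5 rose and 3 fell with sgIgfbp5. The endothelial list was called in neither comparison (camera adjusted p = 0.394 and 0.237). The ATF4 and unfolded protein response list fell at relapse (adjusted p = 0.205 with an estimated correlation) and was split in CUUC-G, where 13 of 28 genes rose, 10 fell and the list was not called (camera adjusted p = 0.23; adjusted p = 0.738 with an estimated correlation). Of its members moving against Kdr and Krt19, Trib3 went from 543 to 40.2 CPM at relapse and from 49.0 to 493.5 CPM with sgIgfbp5, and Ddit3 from 306.1 to 48.1 CPM and from 54.1 to 348.9 CPM.

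Between relapsed and control tumours 10559 genes were called. Genes on the sex chromosomes made up 3.4% of the called genes with a position, against 3.2% of those tested, and immune and vascular cells present in control and missing from relapsed libraries are argued against by a median of 0.0169 CPM over their markers in the control libraries. Different source animals cannot be told apart from relapse, since the lowest control library had 70.4 CPM of Ddx3y and the relapsed libraries had none. A difference in chromosome copy number may contribute: on 8 of 19 autosomes the median log2 fold change left that of all autosomal genes by over 0.1 and beyond 10000 shuffles, by -0.339 on chromosome 15, which is small beside the 2-fold changes, and shuffles ignore that neighbouring genes can be regulated together. Of the 10 splits of the 6 libraries 1, the real one, gave as many genes, and the highest other gave 0 (45 at an unadjusted p under 0.05, edgeR). Every other split mixes relapsed and control libraries, so the difference between them enters its spread and its 0 calls measure no chance level. Moreover, 10 splits are too few for a share under 0.05. An effect of the treatment stays open and untested.

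Between sgIgfbp5 and sgScr CUUC-G 10305 genes were called. Male control tumour cells in the sgIgfbp5 libraries, which share low cytokine and high Cdsn levels with the control tumours, are argued against by the Y-linked genes, whose 32 counts allow a male share of up to 0.455% (upper 95% limit; 0.425% in sgScr). A copy number difference between the populations, for example from growth out of few cells, may contribute here too: 8 of 19 autosomes passed the same rule, by -0.382 on chromosome 16. Of the 3 autosomes that passed in both comparisons 2 moved in opposite directions. The real split was 1 of 10 and the highest other split gave 0 genes (204 unadjusted), but 10 splits are too few for a share under 0.05. The other splits mix sgIgfbp5 and sgScr libraries, so their 0 calls measure no chance level either. Loss of Igfbp5 stays open and untested. Guide and population coincide, so no split of these libraries could separate them.

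The relapse and sgIgfbp5 changes went in opposite directions for 83.4% of the genes called in both. A candidate explanation is that relapsed tumour and sgScr CUUC-G libraries hold the same cell population, which enters the 2 contrasts with opposite signs: their mean log2 CPM correlated across genes at 0.991, against 0.907 for relapsed and control tumours, and 272 of 15366 genes differed 2-fold against 4033. The correlation of fold changes tests a narrower case, with the control, sgIgfbp5 and common populations about equally distant. A range from -0.6 to -0.4 was set for that case beforehand. Pearson's r was -0.669 (-0.665 to -0.652 with each library left out) and Spearman's rho, only just outside, -0.607. The range is a chosen margin, so rho does not decide the case. Pearson's r argues against equal distances only. A common population with the other 2 nearer to each other can give these values too, so it stays open as the whole cause. The mean squared log2 difference between control tumours and sgIgfbp5 CUUC-G was 1.363, against 1.628 between control and relapsed tumours and 1.83 between sgScr and sgIgfbp5. By genes differing 2-fold, control tumours were no nearer to sgIgfbp5 CUUC-G (4050 genes) than to relapsed tumours (4033). Between sgScr and sgIgfbp5 5006 genes differed 2-fold. Whether lower Igfbp5 brings the 2 populations together stays open, as a hypothesis untested here.

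In MGHU3, 1 of the 10 splits, the real one, gave as many transcripts (1156), and the highest other gave 0 (1070 at an unadjusted p under 0.05, edgeR). The other splits mix targeted and sgScr libraries, so their 0 calls measure no chance level, and 10 splits are too few for a share under 0.05.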
